A study of Homo sapiens with 6 samples.

How the data were processed

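RNA of A375 cells, an established human melanoma cell line, was measured on Illumina bead arrays after culture with leflunomide or with DMSO, the solvent control. Per the labels' protocols, cells were seeded at 100000 per flask, grown for 3 days with DMSO or with leflunomide at 25 µM, and their RNA was extracted, cleaned, treated with DNase and labelled as biotinylated cRNA. The labels give 3 arrays per treatment and number them 1 to 3. They do not say whether arrays of a treatment came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

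The deposited intensity values are linear mean bead signals, not normalized between arrays, per the file headers. They were made with GenomeStudio, per the submitters' processing notes, and its version, the genome build and the probe annotation are not given in the sources used here. The file gave 38275 rows, of which 25438 carried a gene symbol that occurred once, so probes of a gene had already been combined by the authors. Beside each signal the authors deposited a detection p-value that compares the row with the negative control beads of the same array. On 32290 rows these p-values were whole multiples of 1/759 on all 6 arrays within a tolerance of 0.001, as a rank among 759 negative control bead types gives. The other rows held p-values that fit no such rank, as a combination over several probes would give. A second deposited table held intensity values of 48803 probes without gene names. Its 6 column means lay between 311.539 and 311.579. Between 72.4% and 74.0% of the bright rows of the first file recurred in the same array's column after multiplication by 1 factor per array, within 2e-06 on the natural log scale. That table was therefore read as the same signals scaled to a common mean on a linear scale, and it was used as an alternative. The column medians of that table were 54.7, 50.4 and 58.3 for the DMSO arrays and 67.8, 54.2 and 93.9 for the leflunomide arrays. Whether anything else was done to it before deposit is not known.

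From the first file, background was corrected with limma 3.58.1 in R 4.3.3 by the normexp model with negative control parameters inferred from the detection p-values, an offset of 16, and quantile normalization between arrays, as in its neqc function. The usual inference over all rows gave negative control SDs of 179 to 249.7 signal units, because combined p-values do not give the rank of a signal. The parameters were therefore inferred from the 32290 rows with ranks, which gave SDs of 5.87 to 13.1. This choice was made before any fold change was computed. Rows with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, used for names alone. Of the named rows, 14193 had a current symbol, 3625 were renamed through a synonym that belongs to a single gene, and 7620 kept the name in the file. A group of 22 symbols had been turned into dates in the file, and none of these was named. Where renaming joined rows, the row with the highest mean was kept, which left 12345 genes.

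Leflunomide was compared with DMSO by limma's linear model with empirical Bayes moderation, without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over all 12345 genes. Fold changes are leflunomide over DMSO, on normalized log2 intensity with the offset, which understates the change of dim genes. A total of 28 gene lists, 8 of them primary, was fixed before the data were examined. The 27 lists with at least 3 tested genes were tested with camera from limma at a preset correlation of 0.01, with adjustment over these 27 lists. The list of endothelial markers had 2 tested genes and was not tested. Each list was also tested with an estimated correlation between its genes. Detected rows per array were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot give a p under 0.1.

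The genes named in the text follow a rule that was also fixed before the data were examined. They are the 12 largest increases and the 12 largest decreases among genes past an adjusted p of 0.05 whose groups did not overlap and whose symbol is not provisional. To these come up to 4 genes of each list with the largest absolute change, whether past the threshold or not, and 9 genes that were always to be given. Any other gene named was chosen after its values were seen. Some results for single genes that the rule names are not given here. A gene not above background on every array of a treatment was to be given as a bound, "at least N-fold", from the mean of the bright group over the mean of the higher of the lowest detected signal and the gene's own signal on each dim array. Where no detection limit is stated, a gene was detected on at least 1 array of each treatment.

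The alternatives were other background corrections, normalizations, detection filters and variance models, an ordinary two-sample test, the replicate number as a block, the second deposited table, other list tests, and leaving out each array in turn. Array weights, and the removal of signals far under background on leflunomide replicate 3, were added after seeing the data. For the detection of genes per array, a threshold of 0.01 was the alternative, and leaving out each array was added after seeing the data. In comparing settings, a gene or list past the threshold in neither setting was counted as alike whatever its sign.

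The tests were checked on simulated values for the leflunomide and DMSO comparison, drawn for the 12345 genes from their means and spread, with the deviations of leflunomide replicate 3 shuffled between genes. With all 6 arrays, limma recovered 46.0% of genes changed 2-fold and 84.0% of genes changed 4-fold, out of 50 genes at each size. Of genes changed 1.5-fold, it recovered 2.0%. Without leflunomide replicate 3 the shares were 90.0% at 2-fold, 98.0% at 4-fold and 60.0% at 1.5-fold. Of the simulated genes that limma called, 0 of 106 were unchanged genes with all 6 arrays and 6 of 197 (3.05%) without leflunomide replicate 3. On the same simulated genes camera called a list of 30 shifted genes and not a list of 30 unchanged genes. The simulated genes varied independently of each other, so this could not check camera's p-values for lists whose genes vary together. The background step, run on 32290 simulated rows with a negative control SD of 6, gave an SD of 5.94. The number of arrays limits the precision of every comparison. Figures were drawn with matplotlib.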

Results

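Gene expression was measured in A375 cells, a human melanoma cell line, after 3 days with 25 µM leflunomide or with its solvent DMSO, on 3 arrays per treatment. Leflunomide inhibits dihydroorotate dehydrogenase, the mitochondrial enzyme of de novo pyrimidine synthesis encoded by DHODH. The comparison asks which transcripts differ in abundance between cells grown with and without the drug. The mean signal per array was 325.2, 370.5 and 317.7 for the DMSO arrays and 261.7, 343.1 and 128.9 for leflunomide replicates 1, 2 and 3. Rows above background at a detection p under 0.05 numbered 13885 ± 119 (SD, n = 3) with DMSO and 12930 ± 997 (SD, n = 3) with leflunomide. The exact two-sided permutation test gave p = 0.1 for this difference, the smallest that 3 arrays against 3 can give. The difference in means was −955 rows with all arrays and −398 rows without leflunomide replicate 3, where p was again 0.1, the smallest possible.

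Leflunomide replicate 3 stood apart from the other 5 arrays. Its normalized log2 values correlated across genes at 0.890 to 0.902 with the other arrays, which correlated with each other at 0.988 to 0.997. It had 11816 detected rows, against 13235 to 14020 on the others. A total of 1506 rows had detection p-values that were ranks and a signal above 1000 on each of the other arrays. Of these, 76 (5.05%) lay more than 4 log2 units under the median shift of these rows on replicate 3. The same count on each of the other arrays, over 743 rows above a signal of 1000 on the remaining arrays, was 0. The remaining arrays included replicate 3, so the 743 rows held none that was missing there. Transcripts of several lists below were among the genes affected. RPL30, a ribosomal protein gene, had a signal of 27.3 on this array, and ATIC, a gene of purine synthesis, had 28.7, while the negative control mean was 36.8 ± 6.52 (SD). Counts of genes past the threshold over all genes are therefore given below also without this array.

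**Figure D1:**
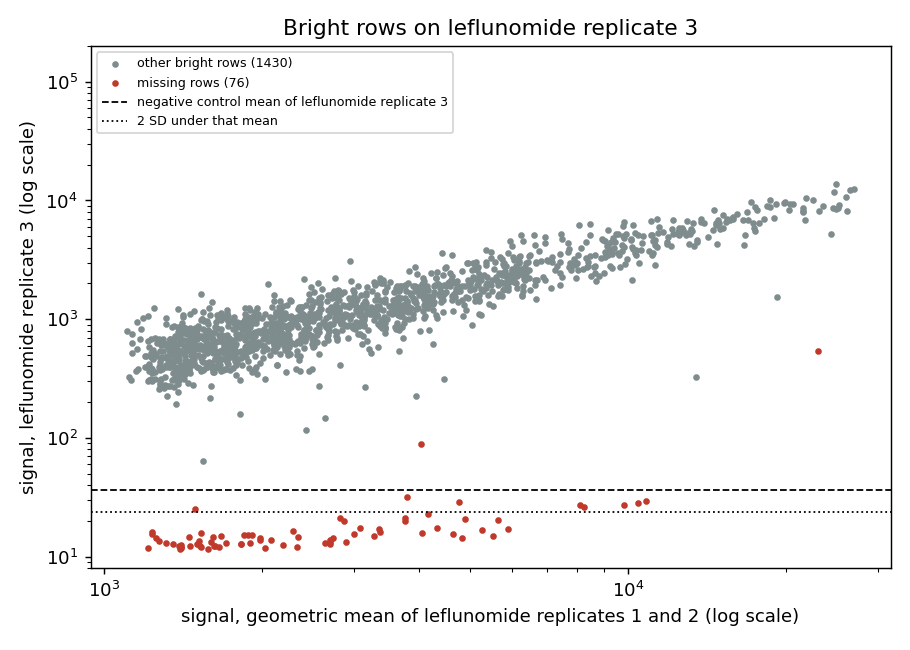
Signal of bright rows on leflunomide replicate 3 (vertical axis, log scale) against the geometric mean of their signals on leflunomide replicates 1 and 2 (horizontal axis, log scale), 1 point per row, with the missing rows in red. The 76 missing rows form a separate band, most of it under the dashed line at the negative control mean of 36.8 signal units, and the dotted line lies 2 SD under that mean.

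The largest decreases under leflunomide exceeded the largest increases in size. IL24, a cytokine of the interleukin 10 family, fell 9.66-fold (log2 fold change −3.27 ± 0.12 SE, limma adjusted p = 0.00056). The transcription factor gene EGR1 fell 6.68-fold (−2.74 ± 0.16, limma adjusted p = 0.0049) and the stress cytokine gene GDF15 fell by 2.70 on the log2 scale (SE 0.10, limma adjusted p = 0.00056). ACTA2, which encodes smooth muscle actin, fell 5.69-fold (−2.51 ± 0.09, limma adjusted p = 0.00056). BTG2, an antiproliferative gene, fell 5.20-fold, IL1RL1, the interleukin 33 receptor gene, 4.43-fold, and CDKN1A, which encodes the cell cycle inhibitor p21, 4.39-fold. GADD45A, IL1B, DAPK1, SERPINB7 and SPRR2D fell between 3.40-fold and 4.22-fold. IL1RL1 was above background on 1 and DAPK1 on 2 of the 3 leflunomide arrays. SPRR2D belongs to a family of near-identical genes, so its probe may not tell them apart.

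Increases were smaller. MIX23, named CCDC58 in the file, rose 3.66-fold (log2 fold change 1.87 ± 0.14 SE, limma adjusted p = 0.010). The pseudogene DUSP5P1 rose 2.48-fold and CBS, which encodes cystathionine beta-synthase, 2.35-fold (limma adjusted p = 0.048 and 0.047). FAM72A, MEOX2, SNORA33, NR2F1 and NMU rose between 2.17-fold and 2.34-fold. The sodium channel gene SCNN1A, the kinase gene PIM1, the histone variant gene H3-3B and the cadherin gene CDH11 rose between 2.01-fold and 2.05-fold. FAM72A and H3-3B have near-identical copies elsewhere in the genome. MEOX2 was above background on 2 of the 3 DMSO arrays.

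Across 12345 genes, limma called 132 at an adjusted p under 0.05, 29 higher and 103 lower with leflunomide. Of these, 13 rose and 67 fell at least 2-fold, and 78.0% of the called genes were lower. In all 132 the 3 leflunomide arrays lay on 1 side of the 3 DMSO arrays, which a call with so few arrays favours, so it adds no support. Such separation occurred in 29.8% of all genes, where chance gives 10%. On the other 5 arrays limma called 2366 genes, 1145 higher and 1221 lower, among them all 132 in the same direction. Of the 2366, 25 rose and 113 fell at least 2-fold. Leaving out any other array in place of replicate 3 left 3 to 5 called genes, all lower, which always included IL24, GDF15 and ACTA2. With the replicate number as a block limma called 4 genes, IL24, EGR1, GDF15 and ACTA2, all lower. Scaling arrays to a common median in place of quantile normalization called 0 genes (limma, with 1675 at an unadjusted p under 0.05) and moved the median of all genes to −0.53.

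**Figure D2:**
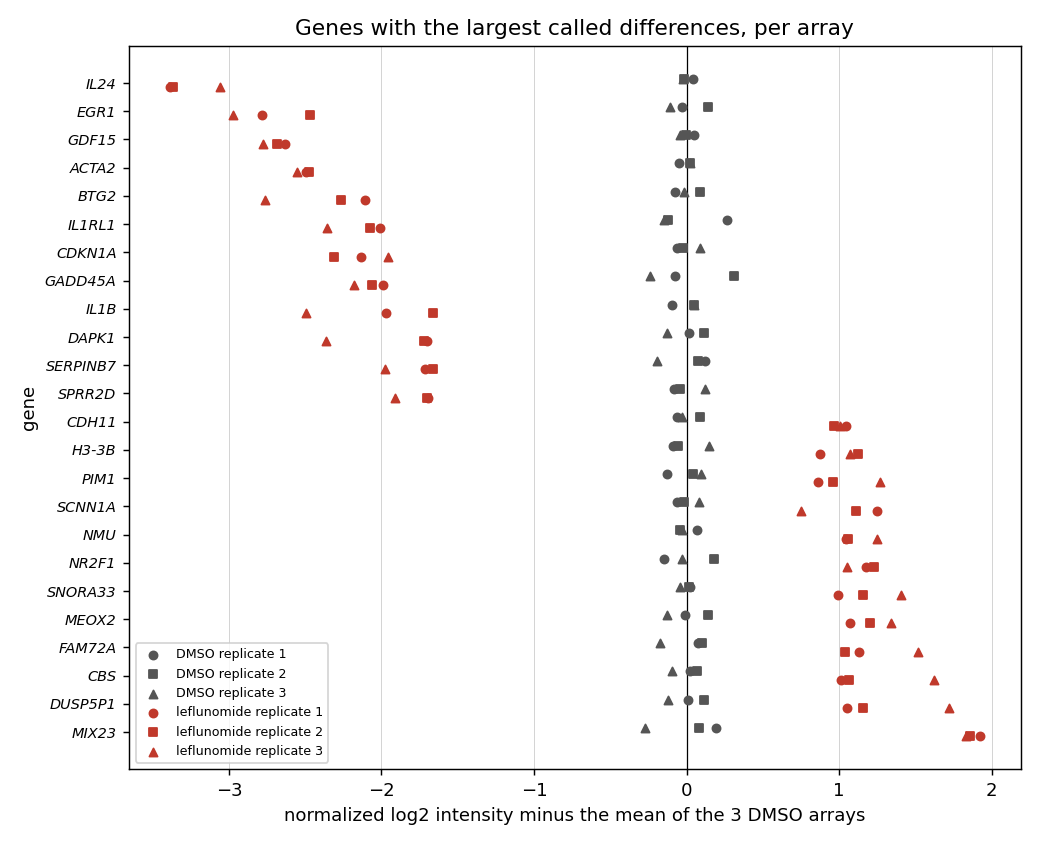
Normalized log2 intensity of each array less the mean of the 3 DMSO arrays (horizontal axis) for the 12 largest decreases and 12 largest increases (vertical axis), with 1 symbol per array. By the rule that chose these genes, the 3 leflunomide arrays (red) lie on 1 side of the 3 DMSO arrays (grey) in each. Their mean runs from −3.27 for IL24 to 1.87 for MIX23.

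Targets of p53, the tumour suppressor and transcription factor, fell as a group. The median of the 23 tested targets was −1.07 on the log2 scale, a 2.10-fold decrease, and camera from limma called the list lower at an adjusted p of 5.92e-17 (mean of the list −1.26). With an estimated correlation the camera adjusted p was 0.021. Past the threshold over all genes, 7 targets fell, none rose and 16 did not pass, and 16 fell when adjusted over the list alone. GDF15, BTG2, CDKN1A and GADD45A are among the 7. With this array left out the median was −1.08, and limma called 21 of the 23 lower and none higher (camera adjusted p = 1.05e-23, and 0.038 with an estimated correlation). PHLDA3 and SESN1 had log2 fold changes of −2.72 ± 1.09 (SE) and −2.36 ± 0.94 over all 6 arrays, with signals of 11.1 and 11.4 on replicate 3. Without that array they were −1.37 and −1.20.

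Genes of mitosis were higher as a group with leflunomide. The median of the 36 tested genes was 0.45, a 1.37-fold increase (camera adjusted p = 2.02e-12), although under median scaling it was −0.17, above the median of all genes at −0.53. With an estimated correlation the camera adjusted p was 0.11. Past the threshold over all genes 1 gene rose, the centromere protein gene CENPA (log2 fold change 0.69 ± 0.10 SE, limma adjusted p = 0.047), chosen after its values were seen, and 35 did not pass. Adjusted over the list alone, 20 rose and none fell, and without leflunomide replicate 3 these counts were 34 and 0. Without leflunomide replicate 3 the median was 0.55, and limma called 33 of 36 higher and none lower, while the list's adjusted p was 0.12 with an estimated correlation. In that comparison the cyclin gene CCNB1 was 2.06-fold higher (limma adjusted p = 0.00010) and the guanine nucleotide exchange factor gene ECT2 1.87-fold (limma adjusted p = 0.00080). With all 6 arrays CCNB1 was at 0.93 ± 0.15 (SE, limma adjusted p = 0.052) and ECT2 at 0.85 ± 0.16 (SE, limma adjusted p = 0.080). The kinase gene TTK and the cyclin gene CCNB2 had signals of 10.1 and 12.7 on replicate 3, and their log2 fold changes went from −0.95 and −1.75 with it to 0.69 and 0.55 without it.

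Genes of DNA replication had a median of 0.26 over 34 tested genes, a 1.19-fold increase (camera adjusted p = 2.59e-05, and 0.11 with an estimated correlation), although under median scaling it was −0.45, above the −0.53 of all genes. None passed limma's threshold over all genes, with 11 at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. On the other 5 arrays the median was 0.33, and limma called 14 higher and 2 lower, or 20 and 2 over the list alone (adjusted p = 0.40 with an estimated correlation). The helicase subunit gene MCM6 was at 0.68 ± 0.12 (SE, limma adjusted p = 0.071) with all arrays and at 0.77 without replicate 3 (limma adjusted p = 0.00021). E2F2, a cell cycle transcription factor gene, was at 0.78 ± 0.16 (SE) with all arrays (limma adjusted p = 0.096). PCNA, the sliding clamp of replication, had a signal of 31.5 on replicate 3, and was at −1.25 ± 1.25 (SE) with it and 0.30 without it.

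Genes of inflammatory signalling were lower. The 23 tested genes of the list of NF-kB targets and cytokines had a median of −0.36 (camera adjusted p = 3.08e-05, and 0.11 with an estimated correlation). Among them 5 fell, none rose and 18 did not pass, and 9 fell and 1 rose when adjusted over the list alone. The 5 were the cytokine genes IL24, IL1B, IL6, IL1A and CSF2, the last pair chosen after their values were seen. IL6 fell 3.37-fold (log2 fold change −1.75 ± 0.25 SE, limma adjusted p = 0.044). CXCL1, with a signal of 11.4 on replicate 3, was at −1.97 ± 1.27 (SE) with it and −0.41 without it. Without that array the median was −0.43, and limma called 14 of the list lower and 2 higher, or 16 and 2 over the list alone (adjusted p = 0.30 with an estimated correlation).

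Interferon response genes had a median of −0.37 over 31 tested genes (camera adjusted p = 4.53e-07, and 0.046 with an estimated correlation). No member passed limma's threshold over all genes, with 14 at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. With replicate 3 left out the median was −0.36, limma called 17 lower and none higher (21 and 1 over the list alone), and the list's adjusted p was 0.12 with an estimated correlation. There, IFI44L, an interferon-induced gene, was 1.85-fold lower and the antiviral synthetase gene OAS2 1.45-fold lower (limma adjusted p = 0.00022 and 0.0055). With all 6 arrays these genes were at −0.57 ± 0.21 (SE) and −0.69 ± 0.20 (SE), not past the threshold (limma adjusted p = 0.25 and 0.16).

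Genes of the pathway that the drug inhibits were not called. Genes of pyrimidine synthesis and salvage had a median of 0.03 and a mean of −0.04 over 28 tested genes (camera adjusted p = 0.63). None passed limma's threshold, with 4 at an unadjusted p under 0.05 and none past it when adjusted over the list alone. DHODH itself was at −0.25 ± 0.17 (SE, limma adjusted p = 0.51). CAD, which encodes the enzyme of the first steps of the pathway, was at −0.11 ± 0.14 (SE, limma adjusted p = 0.70), and UMPS, the gene of its last enzyme, was at −0.67 ± 0.22 (SE, limma adjusted p = 0.20). In the fit of 5 arrays limma called 1 of the list higher and 1 lower. The lower one was UMPS, at −0.59 (limma adjusted p = 0.026), and DHODH was at −0.08. The salvage kinase gene UCK1, the ribonucleotide reductase gene RRM2 and the nucleotidase gene NT5C3A did not pass in either comparison.

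Genes of purine synthesis had a median of 0.07 and a mean of −0.13 over 21 genes and were not called (camera adjusted p = 0.36). None passed limma's threshold, with 2 at an unadjusted p under 0.05 and none past it when adjusted over the list alone, and without leflunomide replicate 3 limma called 1 higher and 1 lower. GART was at −1.50 with all arrays and 0.03 without replicate 3. Genes of UDP-sugar synthesis had a median of −0.13 over 24 genes (camera adjusted p = 0.19), again with none past limma's threshold, 6 at an unadjusted p under 0.05 and none past it when adjusted over the list alone. With replicate 3 left out their median was −0.018 and limma called 4 of them lower, among them CMAS, the gene of sialic acid activation, which was 1.41-fold lower (limma adjusted p = 0.0056) and at −0.61 with all arrays (limma adjusted p = 0.10).

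The list of ATF4 targets and amino acid response genes was not called (median 0.13 over 27 genes, camera adjusted p = 0.27). Its members went both ways. CBS rose, PPP1R15A, the gene of a phosphatase subunit of the stress response, fell 2.33-fold (log2 fold change −1.22 ± 0.10 SE, limma adjusted p = 0.010), and 25 did not pass. Adjusted over the list alone, 5 rose and 2 fell. On the other 5 arrays limma called 8 higher and 2 lower, or 11 and 3 over the list alone. PHGDH, the gene of the first step of serine synthesis, had a signal of 20.2 on leflunomide replicate 3. It was at −1.97 ± 2.13 (SE) with that array and 0.67 without it (limma adjusted p = 0.00080).

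Genes of ribosome biogenesis and MYC targets had a median of 0.09 over 44 genes (camera adjusted p = 0.26), with none past limma's threshold, 6 at an unadjusted p under 0.05 and none past it when adjusted over the list alone. Leaving out leflunomide replicate 3, limma called 7 higher and 1 lower. MYC was at 0.06 (limma adjusted p = 0.88). ODC1, the gene of polyamine synthesis and a known MYC target, was at −0.82 (limma adjusted p = 0.080), and 1.70-fold lower without replicate 3 (limma adjusted p = 0.0018). Ribosomal protein genes had a median of 0.14 over 43 genes (camera adjusted p = 0.0025, and 0.11 with an estimated correlation), and a mean of −0.01. Under median scaling their median was −0.38, above the −0.53 of all genes. None of them passed limma's threshold, with 5 at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone. Left without replicate 3, the list had 6 genes higher and none lower (adjusted p = 0.24 with an estimated correlation). RPL30, RPSA and RPL6 were at −2.76, −2.40 and −1.30 with all arrays and at 0.13, −0.10 and −0.01 without that array, and RPL7 went from −1.21 to 0.61.

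The machinery of transcription elongation was not called (median 0.04 and mean −0.04 over 37 genes, camera adjusted p = 0.89). None of its genes passed limma's threshold, with 3 at an unadjusted p under 0.05 and none past it when adjusted over the list alone. HEXIM1, an inhibitor of the elongation factor P-TEFb, was at −0.23 ± 0.11 (SE, limma adjusted p = 0.36). On the other 5 arrays the median was −0.07, limma called 4 higher and 1 lower, and the histone chaperone gene SSRP1 was at 0.38 (limma adjusted p = 0.048).

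Neural crest factors, which specify the embryonic lineage of melanocytes, were not called as a list (median −0.17 over 20 genes, camera adjusted p = 0.56). None passed limma's threshold over all genes, with 9 at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. SNAI2, a transcription factor gene of this lineage, was at −0.91 ± 0.19 (SE) and did not pass (limma adjusted p = 0.0996). Without leflunomide replicate 3, 4 fell and 4 rose over the list alone, and limma called 4 lower and 2 higher over all genes. The lower ones were SNAI2 (1.76-fold, limma adjusted p = 0.00048), ID2, ID3 and PRDM1, while SOX10 was at −0.17 (limma adjusted p = 0.31). PRDM1 was above background on all 3 DMSO arrays and on none of the leflunomide arrays. In that comparison it was 1.43-fold lower (log2 fold change −0.52 ± 0.12 SE, limma adjusted p = 0.0084, and 0.28 with all 6 arrays), a fitted value, since its leflunomide signals lay above the lowest detected signals.

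Pigmentation genes of melanocytes had a median of −0.15 over 14 tested genes (camera adjusted p = 0.0096, and 0.12 with an estimated correlation). PMEL, which encodes the matrix protein of melanosomes, fell 2.08-fold (log2 fold change −1.06 ± 0.14 SE, limma adjusted p = 0.034). It was above background on 1 of 3 leflunomide arrays, which was replicate 3. Without that array PMEL was at least 2.39-fold lower. The other 13 did not pass over all genes, and 4 fell when adjusted over the list alone. RAB38, APOD and CDK2 were between −0.55 and −0.63, and with PMEL were the 4 called lower without leflunomide replicate 3 (list adjusted p = 0.024, and 0.30 with an estimated correlation). Of these, CDK2 encodes a cell cycle kinase and APOD a secreted apolipoprotein, so the list does not hold pigmentation genes alone. Under median scaling the list's call was lost (median −0.62, camera adjusted p = 0.13). MITF was detected on too few arrays to be tested.

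Genes of the undifferentiated melanoma state were not called (median −0.08 over 21 genes, camera adjusted p = 0.56). PDGFRB, a growth factor receptor gene of that list, rose 1.87-fold (limma adjusted p = 0.032), 20 did not pass, and 1 rose and 3 fell when adjusted over the list alone. In the fit of 5 arrays 4 were higher and 4 lower, and the median was 0.06. Output genes of the MAPK pathway had a median of −0.19 over 22 genes (camera adjusted p = 0.12), with EGR1 lower past the threshold, 21 not past it, and 1 lower when adjusted over the list alone. Without replicate 3 of leflunomide that list was called lower (camera adjusted p = 0.041, and 0.57 with an estimated correlation), with 7 members lower and 1 higher. Adjusted over the list alone, 7 were lower and 3 higher there.

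**Figure D3:**
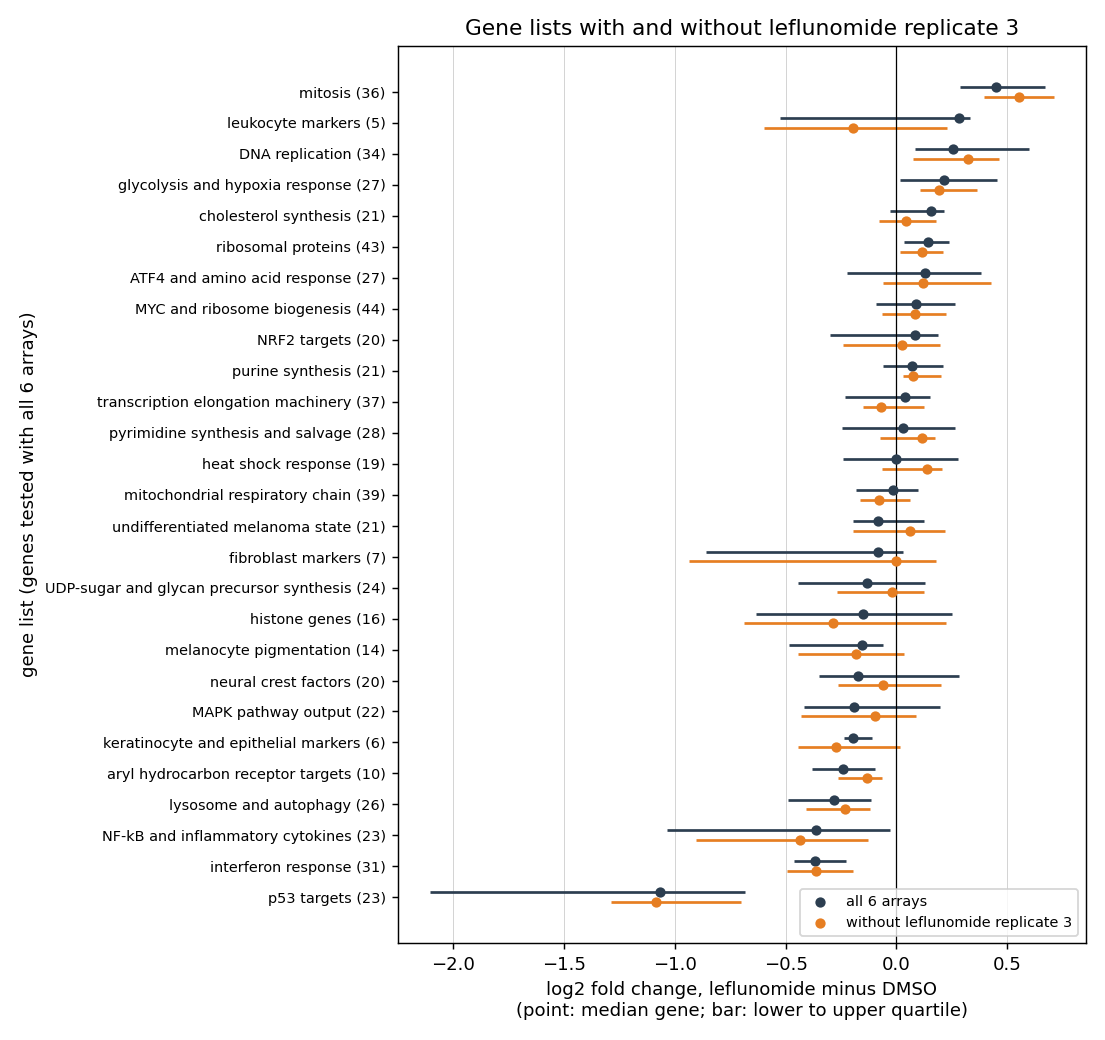
Median log2 fold change of the tested genes of each list (points) with lower and upper quartiles (bars) on the horizontal axis, for all 6 arrays (dark) and without leflunomide replicate 3 (orange), and the number of genes tested after each list name. The p53 targets lie lowest, at medians of −1.07 and −1.08, and mitosis genes highest, at 0.45 and 0.55. Under median scaling, which is not drawn, the mitosis median was −0.17, above the −0.53 of all genes.

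Lysosome and autophagy genes were lower as a group, with a median of −0.28 over 26 genes (camera adjusted p = 0.00059, and 0.12 with an estimated correlation). WIPI1, an autophagy gene, fell 1.54-fold (limma adjusted p = 0.045), 25 did not pass, and 3 fell when adjusted over the list alone. On the other 5 arrays limma called 8 lower and 1 higher, or 11 and 1 over the list alone (adjusted p = 0.40 with an estimated correlation). Genes of glycolysis and the hypoxia response had a median of 0.21 over 27 genes, or −0.38 under median scaling, above the −0.53 of all genes (camera adjusted p = 0.0011). With an estimated correlation the adjusted p was 0.37. None passed limma's threshold, with 8 at an unadjusted p under 0.05 and none past it when adjusted over the list alone. The carbonic anhydrase gene CA9, induced by hypoxia, was at 1.09 (limma adjusted p = 0.0996) and was 1.84-fold higher without replicate 3 (limma adjusted p = 0.0014), where limma called 8 of the list higher and none lower, or 10 and none over the list alone.

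Targets of the aryl hydrocarbon receptor, which leflunomide is known to activate, had a median of −0.24 over 10 genes (camera adjusted p = 0.031). That call held in 11 of 19 alternatives (adjusted p from 0.0035 to 0.37) and was lost, among others, with an estimated correlation (adjusted p = 0.37), without leflunomide replicate 3 (adjusted p = 0.12) and under median scaling (adjusted p = 0.24). SERPINB2 of that list fell 2.61-fold (limma adjusted p = 0.028), 9 did not pass, and 1 fell when adjusted over the list alone. CYP1A1, the classical induced gene, was at −0.59 (limma adjusted p = 0.16). In the fit without replicate 3 limma called 2 lower and none higher, or 3 lower and 1 higher over the list alone. CYP1A1 was at −0.50 there (limma adjusted p = 0.0093).

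Targets of NRF2, the factor of the oxidative stress response, were not called (median 0.08 and mean −0.04 over 20 genes, camera adjusted p = 0.88, direction down). AKR1B10, a reductase gene of that list, fell 1.84-fold (limma adjusted p = 0.024), 19 did not pass, and 1 fell when adjusted over the list alone. Without leflunomide replicate 3, limma called 5 lower and none higher over all genes, or 5 lower and 3 higher over the list alone. Cholesterol synthesis was not called (median 0.16 over 21 genes, camera adjusted p = 0.24), and the median was 0.04 on the other 5 arrays (camera adjusted p = 0.43). Genes of the respiratory chain (median −0.02 over 39 genes) and of the heat shock response (median −0.00081 and mean −0.10 over 19 genes, direction up) were not called, at camera adjusted p of 0.60 and 0.89. None of them passed limma's threshold, with 4 and 3 at an unadjusted p under 0.05 and none past it when adjusted over each list alone. With replicate 3 left out each list had 2 higher and 2 lower.

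Markers of other cell types were in part detected. The mean normalized log2 intensity with DMSO was 11.82 for ACTA2, 10.55 for the keratin gene KRT18 and 9.87 for the lysosomal gene CD68. Of 12 fibroblast markers 7 were tested, with a median of −0.08 and a mean of −0.56 (camera adjusted p = 0.031, and 0.32 with an estimated correlation). ACTA2 fell, 6 did not pass, and 3 fell when adjusted over the list alone. That call held in 12 of 19 alternatives (adjusted p from 1.77e-08 to 0.32) and was lost, among others, without leflunomide replicate 3 (camera adjusted p = 0.0996, with 3 lower) and under median scaling (adjusted p = 0.24). Adjusted over the list alone, 3 were lower and 1 higher without replicate 3. Keratinocyte and epithelial markers had a median of −0.19 over 6 tested genes of 13 (camera adjusted p = 0.27), with none past limma's threshold, 1 at an unadjusted p under 0.05, none past it over the list alone, and 2 lower without replicate 3. Leukocyte markers had a median of 0.28 over 5 tested genes of 12 (camera adjusted p = 0.89), with none past limma's threshold, 3 at an unadjusted p under 0.05 and 2 lower when adjusted over the list alone. On the other 5 arrays their median was −0.19 over 4 genes, with 1 higher and 2 lower. The endothelial markers PECAM1 and TEK, too few for a test, were at −0.21 and −0.03 with all arrays and at 0.12 and 0.05 without replicate 3, and neither passed.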

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

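Rows of the deposited intensities without a gene symbol took no part in the comparisons of genes, and they also held differences between the treatments. With all 6 arrays, limma called 2 of 1254 detected rows of this kind at an adjusted p under 0.05, 0 higher and 2 lower with leflunomide (125 at an unadjusted p under 0.05, 55 of them higher). Without leflunomide replicate 3 it called 132 of 1163, of which 53 were higher and 79 lower. The rows are not named here, and no explanation was tested.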

How the results depend on the processing

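Array weights, the removal of low signals on leflunomide replicate 3 and the count of detected rows with an array left out were chosen after seeing the data. The p53 list stayed lower and past the threshold in all 19 alternatives (adjusted p from 1.90e-47 to 0.021). The interferon list did so too (1.45e-10 to 0.046). NF-kB targets (adjusted p from 1.45e-12 to 0.11), mitosis (from 5.70e-20) and DNA replication (from 1.21e-06, both to 0.11) were past it in 18 of 19 and pigmentation in 17 of 19 (up to 0.13), and pyrimidine, MYC, elongation and neural crest lists in none. With an estimated correlation the calls for mitosis (median 0.45), replication (0.26), NF-kB targets and ribosomal proteins were lost (camera adjusted p = 0.11 each). So were those for pigmentation (−0.15) and lysosome genes (0.12 each), and for glycolysis, aryl hydrocarbon receptor and fibroblast lists (0.32 to 0.37). That test takes the correlation between genes from these data in place of the preset 0.01, so the lost calls rest on the preset. The p53 and interferon lists kept theirs (0.021 and 0.046). Most of the 19 alternatives keep the preset correlation. An estimated correlation with leflunomide replicate 3 also left out is not among the 19. It gave camera adjusted p of 0.12 for the interferon list and 0.038 for p53 targets. Under median scaling the call for pigmentation (−0.62, adjusted p = 0.13) was lost, and the cause was not tested.

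The number of called genes depended on leflunomide replicate 3. Without 1 array, the called genes ranged from 3 to 2366, those higher from 0 to 1145, those lower from 3 to 1221, those 2-fold higher from 0 to 25 and those 2-fold lower from 3 to 113. The upper ends belong to the comparison without leflunomide replicate 3, and the cause of the low counts without another array was not tested. Array weights gave that array 0.0685 (the others 1.20 to 2.84) and called 2549 genes (1222 higher, 1327 lower, 23 and 108 of them 2-fold). Setting its signals under background as missing called 204, with 53 higher. All 132 genes were called in both and without replicate 3, but these fits reuse the same arrays and are no independent check.

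Cyclic loess called 323 (91 higher, 232 lower, 20 2-fold higher). Median scaling called 0 in each count (1675 at an unadjusted p under 0.05). The ordinary two-sample test called 39 (13 higher, 26 lower, 2 and 12 of them 2-fold). Without background correction 2 genes were 2-fold higher and 35 lower, and with an offset of 50 these were 2 and 31. Without a filter 47 genes were higher, and with a variance trend 14 were. The authors' value table gave 57 probes of 48803 (1 higher, which was 2-fold, and 56 lower), the median of all probes at 0.31, and 1048 without replicate 3 (276 higher, 772 lower). Of the called, 98.2% were lower there, against 78.0% in the gene comparison, 71.8% with cyclic loess and 51.6% without replicate 3. The causes were not tested except where stated.

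The replicate number as a block called 4 genes, 0 higher and 4 lower, all 4 lower by 2-fold: IL24, GDF15, ACTA2 and EGR1. Deviations of same-numbered arrays correlated at −0.0086, 0.21 and 0.22, which does not decide whether the numbers pair the arrays, since leflunomide replicate 3 dominates the deviations of its group (root mean square 0.676, against 0.340 and 0.355). Genes called without leflunomide replicate 2 were these 4 and CDKN1A.

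With 1 array left out PHGDH ranged from −3.29 to 0.67, CCNB2 from −2.89 to 0.55, TTK from −1.78 to 0.69 and RPL7 from −2.18 to 0.61. These genes turned from a negative value that was not called to a called increase without leflunomide replicate 3, where their signals had lain under background. Of the other comparisons of named genes over these settings, 1949 kept their side of the threshold, 252 lost and 131 gained a call. Detected rows kept the direction at a threshold of 0.01 and with any array left out (differences from −1360 to −398). Averaging probes of a gene and a slide as a block were not run, because the file had 1 row per gene and no slide was given. The value table holds no gene names, so it gave no lists. On leflunomide replicate 3 the mean signal above background was 2.59 times background, against 3.75 to 5.41 on the others, which limits what can be said of dim genes.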

Other observations

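A pair of histone genes went opposite ways. Their list was not called (median −0.15 over 16 genes, camera adjusted p = 0.33), and 14 of its genes did not pass over all genes. Called by limma were H4C8, a core histone gene, 2.78-fold lower (log2 fold change −1.47 ± 0.17 SE, adjusted p = 0.027), and H3-3B, a replacement variant gene, higher. Adjusted over the list alone 5 fell and 3 rose. Without leflunomide replicate 3, limma called 8 lower and 3 higher, with a list median of −0.29 (camera adjusted p = 0.0996), H2AC18 at −0.95 and H2BC21 at −0.76 (adjusted p = 0.00021 and 0.0037). H4C8 was at −1.52 there. Probes of core histone genes may be shared by near-identical copies, which was not tested.

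In the weighing that follows, the tests of missing signals, of exchanged labels and of cell density were chosen after the results were seen. For exchanged labels CYP1A1 alone was looked at first (−0.50 without leflunomide replicate 3, adjusted p = 0.0093), and the whole list was then used, because a single dim gene decides nothing. The bound for the test of cell density was revised after its values were seen, because members that go both ways decide nothing. The test of a dimmer array replaced an earlier one that only recounted the missing rows. For the count of called genes, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 132 genes and was the 1 split of 10 with as many, and the highest other split called 0 (limma, with at most 828 genes at an unadjusted p under 0.05).

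Bright transcripts were missing on leflunomide replicate 3. Loss of these transcripts from the cells would leave their probes at the level of the negative controls. The median signal of the missing rows was 14.6, under the negative control mean of 36.8 by more than 2 SD. Of the 76 rows, 66 (86.8%) lay below that bound of 23.8. A dimmer array as a whole would likewise bring signals down to the level of the negative controls and not below it. Both arguments rest on the same 66 rows and cover these alone. RPL30 and ATIC, at 27.3 and 28.7, lay above the bound. The share of 86.8% is no measure of support. Missing rows were picked by a fall of more than 4 log2 units under the median shift, which favours signals under the controls. A local fault of that array, or a fault in how its signals were extracted or summarised, may remain, and neither was tested.

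Lower p53 targets with higher mitosis genes go against what depletion of pyrimidines is known to do, since it activates p53. Leflunomide replicate 3 is argued against as the source of the lower p53 targets, because without it their median was −1.08 and the list kept its call. An exchange of the treatment labels on all arrays could not be excluded: aryl hydrocarbon receptor targets, which the drug should raise, had a median of −0.13 without that array and no call (camera adjusted p = 0.12, and from 0.0035 to 0.37 over all alternatives). Sparser cells in the leflunomide flasks may also contribute, and 18 tested targets of YAP, a factor more active in sparse cells, went both ways (median −0.011, quartiles −0.18 and 0.18, 3 higher and 1 lower). An effect of the drug itself stays open as a hypothesis, since no further treatment or culture separates it from these.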
